A study of Ciona robusta with 6 samples.

How the data were processed

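Gene expression was measured by RNA-seq in 6 libraries from whole embryos of Ciona robusta, 3 from embryos that received Cas9 with a guide against Brachyury (CrBra) and 3 from embryos that received Cas9 with a guide against GFP (CrGFP). Per the labels' protocols, each sample held 50 to 85 embryos at Hotta stage 14, grown at 21 degrees Celsius, and libraries were made with a stranded mRNA kit. The submitters' processing notes name TopHat2, version 2.9.8b, and DESeq, version 1.8.1. These are given as written there and could not be checked, and the regularized log transform is generally known from DESeq2. The strand setting of the counting, the counting tool and the genome build were not given in the sources used here. The series' design text calls the replicates biological.

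The deposited table holds 15284 gene models under KH2012 identifiers, and each model has 2 blocks of 6 columns. The first block holds a normalised signal, which per the file headers is the count normalised to library size. The totals of these columns run from 13627742 to 14896910, so the factors are not the libraries' total counts. The second block holds regularized log2 values of the same counts, per the file headers, as deposited by the authors. Within every column of the first block, 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.01 reads. Whole reads were therefore recovered, and they summed to between 13191537 and 16094085 per library. A count of 0 in a library allows a level of up to 3 reads, which is 0.186 to 0.227 CPM in these libraries and covers counting error only. All 12 columns of values were matched to samples by name, and 0 columns were left unused.

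The table gives identifiers only. None of them (0 of 15284) matched the RefSeq gene table of the same species that was used here, whose entries carry other identifiers. The 10 gene lists chosen before the data were examined were notochord effectors, notochord regulators, muscle, endoderm, epidermis, nervous system, mesenchyme and heart, germ line, p53 and cell death, and planar polarity and Wnt. Of their 146 members, 0 could be matched, so no list was tested and no marker of another cell type could be read. GC content, gene length, position and neighbouring or antisense genes were not analysed here for the same reason. KH.S1404.1 is taken as Brachyury from general knowledge of this gene model set and not from the table, so its name could not be checked against the data used here.

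For raw counts, the plan's first choice was an edgeR quasi-likelihood test with TMM. Since the deposited values are not raw counts, the limma test planned for that case was used. Values were transformed to log2(value + 1), gene models with a value of at least 10 in at least 3 libraries were kept (11953, with 3331 left out), and CrBra was compared with CrGFP in limma 3.58.1 with a mean-variance trend in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all tested models, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, where the size of the pseudocount affects the change of low gene models. Tests are two-sided. A second planned fit added the replicate number as a block.

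The plan used no covariate in the main fit and held the replicate block as an alternative. Whether the replicate numbers pair the libraries was decided by a rule on the correlations alone, which that plan did not hold. The correlations and the calls of both fits were first computed in the same step. Deviations from the group means correlated at 0.86, 0.88 and 0.82 between CrGFP and CrBra libraries of the same number. Between libraries of different numbers they correlated at -0.57 to -0.30. Deviations cancel out over the 3 libraries of a group, so high same-number correlations bring negative ones between different numbers. The labels give the numbers and do not say what they share. Because all 3 same-number correlations exceeded 0.1, the numbers were treated as pairing the libraries, and the blocked result is printed beside the unblocked one.

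Alternatives planned before the data were examined were DESeq2 or upper-quartile size factors in edgeR 4.0.16, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, a 1% threshold, a minimum fold of 1.5 and leaving out each library. The edgeR, DESeq2 and voom fits used the recovered whole reads. Alternatives added after the data were seen were edgeR with TMM, pseudocounts of 0.5 and 5, TMM or upper-quartile scaling before limma, the deposited regularized log values, each of these with the replicate block, and the blocked fit without each pair. For edgeR with TMM, the addition was its use on recovered reads, since the plan held it for raw counts.

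The naming rule, fixed before the data were examined, takes at most 2 falling and 2 rising identifiers when no source names them. They must pass the 5% threshold with a log2 fold change of at least 1 in size and with groups that do not overlap. No gene model met it in the unblocked fit, so it was applied to the blocked fit, a choice made after the data were seen.

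The fits were tested on simulated counts for the same 11953 gene models and depths, with the measured differences between replicate numbers kept and 200 models changed. For the CrBra against CrGFP comparison, unblocked limma recovered 26% of models lowered 3-fold (log2 fold -1.58) and 10% of those lowered 2-fold (log2 fold -1). Blocked limma recovered 96% and 84% of them, and called 17 unchanged models among 205 calls. Blocked edgeR recovered 98% and 88% of them and called 32 unchanged models among 223 calls, so both blocked fits, edgeR more so, exceeded the nominal 5% in this simulation. For models raised 2-fold (log2 fold 1), limma recovered 8% without the block and 96% with it, and edgeR 4% and 96%.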

Results

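The series compared whole embryos of Ciona robusta, a tunicate whose larva has a notochord, after Cas9 ribonucleoprotein was injected into unfertilized eggs with a guide RNA against either Brachyury or GFP. Brachyury is a T-box transcription factor of the notochord lineage, and GFP is not a gene of this species, so the GFP guide served as the control. Embryos were collected at Hotta stage 14, a neurula stage, in 3 replicates per guide. CrGFP replicates 1, 2 and 3 held 14337635, 14654814 and 14157457 reads, and the CrBra replicates held 16094085, 13191537 and 14159906. Reads were detected for 13924 to 14067 of the 15284 gene models per library, and 527 models had no read in any library. The 10 most abundant models took 4.35% to 5.01% of the reads in each library. Values below are counts that the authors divided by 1 factor per library, and the deposited totals still differ, from 13627742 to 14896910.

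The largest differences between libraries followed the replicate number and not the guide. The first 2 principal components of log2(value + 1) carried 51.5% and 36.8% of the variance, and on both the CrGFP and CrBra libraries of the same number lay side by side. Among 11953 tested gene models, 8772 (73.4%) differed among the replicate numbers at an adjusted p under 0.05 in limma with the guide as a covariate, and 545 of these ranged by at least 4-fold between numbers. The biological coefficient of variation estimated by edgeR was 31.3% when the libraries of a group were treated as plain replicates. It was 6.43% within the pairs that share a number.

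**Figure D1:**
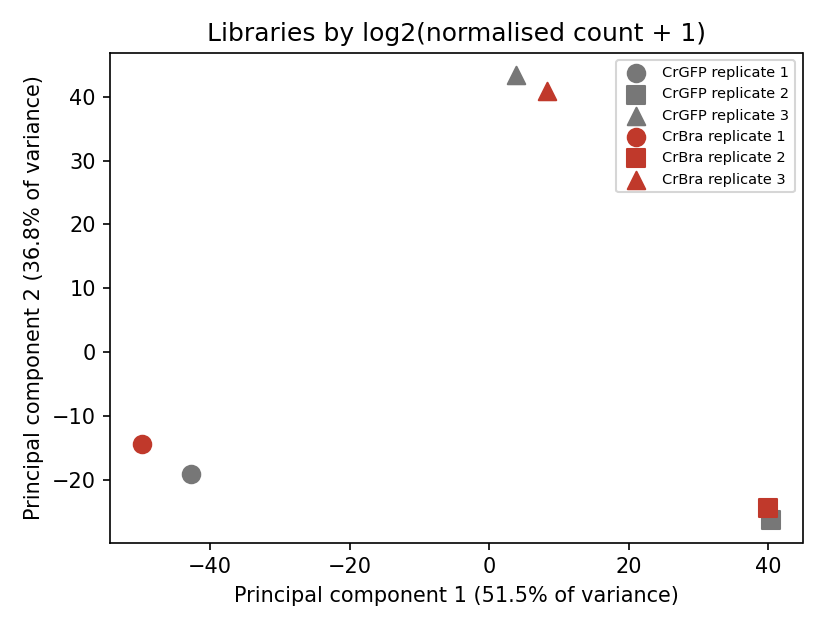
Principal components 1 and 2 of log2(normalised count + 1) over 11953 gene models, with 1 point per library, the colour giving the guide and the shape the replicate number. The libraries of each number lie together, and the components carry 51.5% and 36.8% of the variance.

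The first comparison concerned the targeted gene. KH.S1404.1, the model taken here as Brachyury (an identity the table itself does not give), was lower in all 3 CrBra libraries than in any CrGFP library. Its normalised count was 863 ± 249 (SD, n = 3) in CrGFP and 272 ± 58.3 (SD, n = 3) in CrBra. The CrGFP libraries held 980, 573 and 1040 of its reads and the CrBra libraries 352, 184 and 306. Within the pairs, the CrBra library kept 31.4%, 35.3% and 29.6% of the level of its control. The log2 fold change was -1.64, with a standard error of 0.28 without the replicate block and of 0.076 with it. In limma the fall did not pass over all gene models without the block (adjusted p = 0.608) and passed with it (adjusted p = 8.89e-05). The limma p adjusted over the list alone, a list of this 1 gene, was 0.00066 without the block. An exact permutation test of 3 against 3 exchangeable libraries cannot give a two-sided p below 0.1, and an exact test that exchanges labels within the 3 pairs cannot give one below 0.25. A Cas9 cut alters the gene's DNA and need not lower its transcript, so this level does not measure how many alleles were edited.

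The second comparison asked which other transcripts differed between embryos with the Brachyury guide and controls. Within the replicate pairs, 46 gene models fell in CrBra embryos and 2 rose, in limma with the replicate number as a block. All 46 were lower in each of the 3 pairs, and both risen models were higher in each. These models were chosen on the same pairs, so this agreement in direction is not separate evidence. The falls had a median log2 fold change of -1.42 and ranged from -2.80 to -0.33, with 26 models lowered by at least 2-fold and 4 of those by at least 4-fold. The unblocked limma fit was the planned main fit for values that are not raw counts. Without the block, limma called 0 models at the same threshold, with a lowest adjusted p of 0.196. In that fit 60 models had an unadjusted p under 0.05, 53 lower and 7 higher. By chance 598 would be expected if the tested libraries were independent draws, but libraries of the same number deviate together. In the blocked limma fit, 570 models had an unadjusted p under 0.05, also fewer than 598. Without the block, edgeR and limma-voom also called 0, and DESeq2 called 21, all of them among the 48 of the blocked limma fit.

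Fallen models were found at low, middle and high expression. They made up 4 of the 2935 tested models with a mean control value under 100, 25 of the 5457 with one from 100 to 1000 and 17 of the 3561 with one of 1000 or more. Of the 17 most abundant, 5 fell by at least 2-fold. Of these, KH.L37.39 passed blocked edgeR (adjusted p = 3.97e-06). KH.L20.18, KH.C1.832 and KH.C3.21 did not (adjusted p = 0.0738, 0.517 and 0.227), and neither did KH.C7.261. KH.L20.18 and KH.C1.832 also count among the models lowered by at least 4-fold. Together the 46 models took 0.42% ± 0.029 (SD, n = 3) of the normalised total in CrGFP and 0.237% ± 0.023 (SD, n = 3) in CrBra, although these models were chosen on the same libraries. KH.S1404.1 was itself one of the 46, and 15 of the other 45 had a larger fall than it did. In 36 of the 46 the CrGFP and CrBra values did not overlap. Over all tested models the groups did not overlap in 1.78%, against the 10% that chance gives for 3 against 3 independent libraries.

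**Figure D2:**
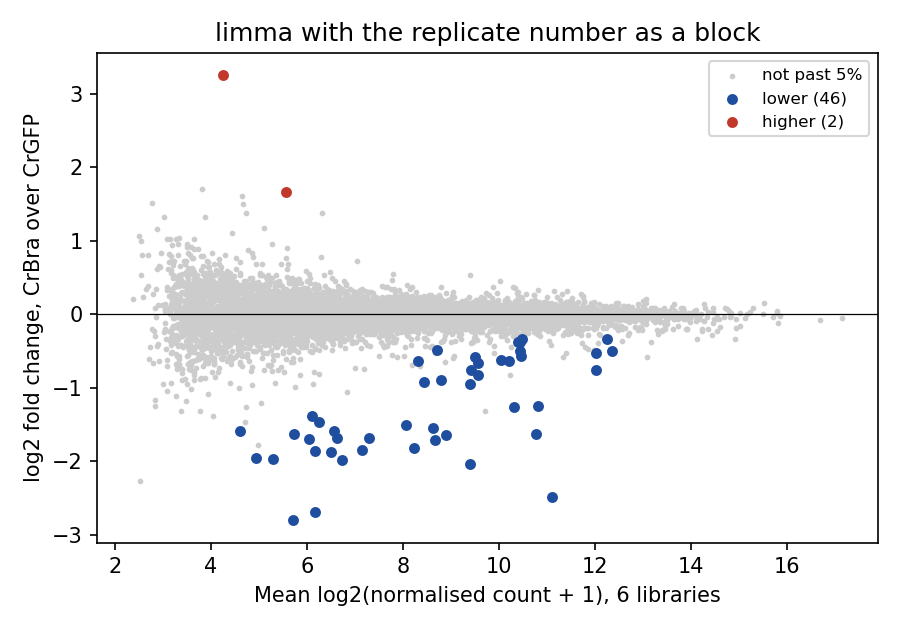
The log2 fold change of CrBra over CrGFP against the mean log2(normalised count + 1) of the 6 libraries, with 1 point per tested gene model. Blue points are the 46 models that fell and red points the 2 that rose in limma with the replicate block; grey points did not pass the 5% threshold.

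By the naming rule, the fallen models with the lowest p in the blocked fit were KH.L37.39 and KH.S1404.1. KH.L37.39 had a normalised count of 2770 ± 458 (SD, n = 3) in CrGFP and 1180 ± 263 (SD, n = 3) in CrBra. The CrBra libraries kept 39.1%, 44.5% and 43.3% of its control level in pairs 1, 2 and 3. Its log2 fold change was -1.24 with a standard error of 0.055 in the blocked limma fit (adjusted p = 8.89e-05), and the adjusted p was 0.504 without the block. The table pairs neither identifier with a name, and position, exon structure and function of KH.L37.39 were not analysed here.

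The 2 models that rose were KH.C2.91 and KH.C5.34, both at low levels. KH.C2.91 had a normalised count of 25.9 ± 6.18 (SD, n = 3) in CrGFP and 83.7 ± 17 (SD, n = 3) in CrBra. Its log2 fold change was 1.66 with a standard error of 0.24 in the blocked limma fit (adjusted p = 0.0322, and 0.958 without the block). With the block, its call was lost in limma with no low-value filter (log2 fold change 1.66, adjusted p = 0.111) and without replicate 2 (1.45, adjusted p = 0.23). Neither risen model passed the blocked limma fit at a 1% threshold or against a minimum fold of 1.5, and neither was tested under the filter of 5 CPM. KH.C5.34 had 3, 28 and 1 reads in CrGFP replicates 1, 2 and 3, and 48, 85 and 48 in the CrBra replicates. Its blocked adjusted p was 0.0395 in limma and 8.36e-05 in DESeq2, but 0.203 in edgeR and 0.104 in limma-voom, so the call depended on the tool. It was also lost in blocked limma with no low-value filter (adjusted p = 0.128) and with a pseudocount of 0.5 (adjusted p = 0.0516). Its log2 fold change was 3.25, 3.19, 2.62 and 2.84 in the 4 tools, in the same order. It was 3.41, 1.70 and 4.63 within pairs 1, 2 and 3, and in unblocked limma it was 4.38 without CrGFP replicate 2 and 2.45 without CrGFP replicate 3.

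**Figure D3:**
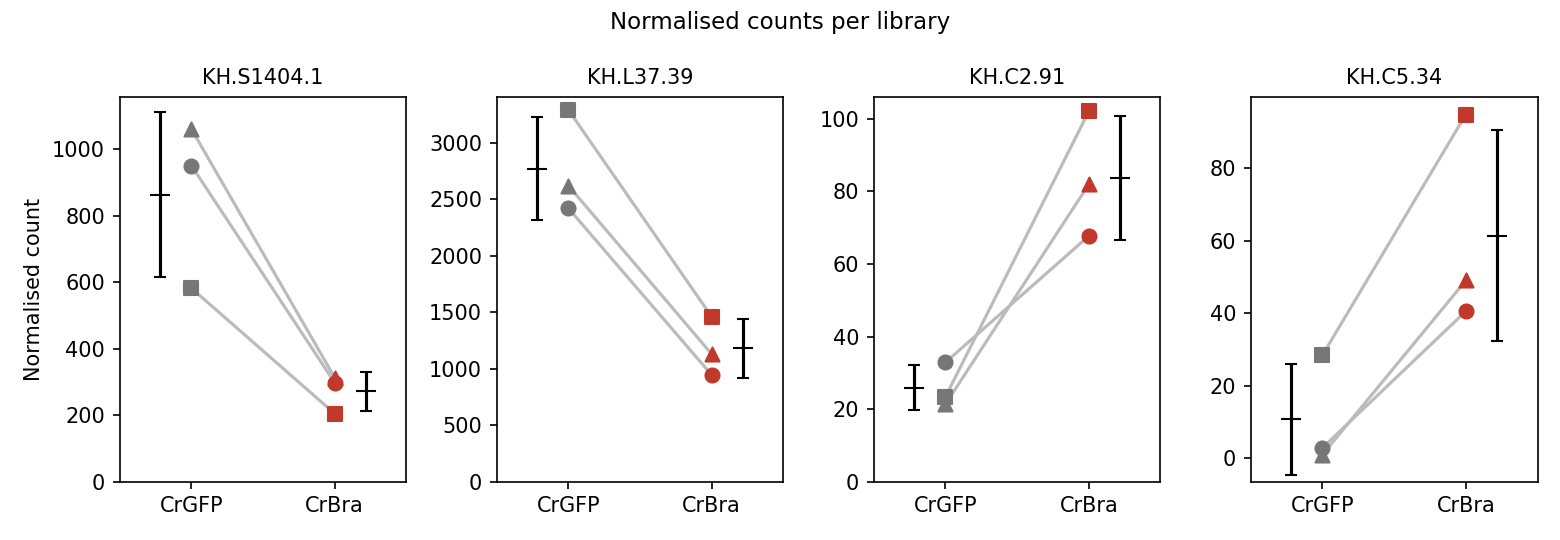
Normalised counts of the 4 named gene models, with 1 point per library, a grey line joining the libraries of each replicate number (circle 1, square 2, triangle 3) and black bars for the mean and SD of each group of 3. KH.S1404.1 and KH.L37.39 are lower, and KH.C2.91 and KH.C5.34 higher, in each CrBra library than in its paired control.

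The blocked calls were compared between tools, which used the same libraries and so are not independent evidence. edgeR called 61 models, 53 lower and 8 higher, and shared 40 with limma. DESeq2 called 58 and shared 44, and limma-voom called 54 and shared 47. All 4 tools called 37 models, of which 36 were lower and 1, KH.C2.91, was higher. The fold of at least 2 was also counted without any model of the spread. In all 3 pairs, 29 models were lower by at least 2-fold and 4 were higher, and 25 of the 29 and 2 of the 4 were among the blocked calls. When the guide labels of any single pair were exchanged, at most 1 model met the same condition, against 33 with the true labels. A model that met it with the true labels cannot meet it after such an exchange. With 3 pairs the labels have 4 such arrangements, too few for a share under 0.05.

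The count of blocked calls depended on which pairs entered the fit. It was 88 (66 lower) without replicate 1, 25 (24 lower) without replicate 2 and 100 (88 lower) without replicate 3. Only a single residual degree of freedom per model remained with 2 pairs left. These counts therefore compare poorly with the count from all 3 pairs.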

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

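The blocked fits other than limma at 5%, and the fits with edgeR TMM, other pseudocounts, rescaled limma or regularized log values, were chosen after the data were seen. The plan held edgeR with TMM for raw counts, and its use on recovered reads was the later choice. Without the replicate block, 0 gene models were called in every setting run, including the fits without each single library, except in DESeq2, which called 21 (20 lower, 1 higher). The unblocked alternatives that gave 0 calls had 30 to 112 models at an unadjusted p under 0.05. With the replicate block, limma called 48 models (46 lower, 2 higher). Other blocked fits on the recovered reads called 61 (53 lower, 8 higher) in edgeR with DESeq2 size factors or with TMM, 53 (48 lower, 5 higher) in edgeR with upper-quartile factors, 58 (55 lower, 3 higher) in DESeq2 and 54 (52 lower, 2 higher) in limma-voom. Blocked limma called 46 (45 lower, 1 higher) with a pseudocount of 0.5, 54 (51 lower, 3 higher) with a pseudocount of 5, 46 (44 lower, 2 higher) after TMM or upper-quartile scaling, and 53 (49 lower, 4 higher) on the deposited regularized log values. It called 27 with no filter and 33 with at least 5 CPM, all of them lower. It called 26 at a 1% threshold and 14 against a minimum fold of 1.5, again all lower, as fewer models can pass these thresholds. Without each pair the blocked calls ranged from 25 to 100, the lower ones from 24 to 88 (66 without replicate 1) and the higher ones from 1 to 22 (12 without replicate 3), and with 2 pairs left a single residual degree of freedom per model remains. The cause of these shifts was not tested. The log2 fold change of KH.S1404.1, the model taken as Brachyury, passed the threshold in DESeq2 without the block (-1.66) and in the blocked fits (the 1% and minimum-fold settings gave counts only), at -1.63 to -1.66 over the tools, filters, scalings and pseudocounts (-1.64 and -1.65 in most), at -0.91 on the regularized log values, which are shrunk, and from -1.58 to -1.71 without each pair. Without the block and without 1 library it lay between -1.90 and -1.45 and did not pass. No named model changed sign in the settings that gave it a value; the 5 CPM filter left out both risen models, and the 1% and minimum-fold settings gave counts only. All scalings left the median log2 fold change of the tested models within 0.1 of 0. No gene list could be tested, so none has an alternative.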

Other observations

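Of the tests here, the scaling tests of the excess of falls and the counts over splits of the libraries were chosen after the result was seen. Ranges of at least 2-fold between replicate numbers were found in 2435 gene models that differed among numbers, and the median range over all tested models was 0.56 on the log2 scale. Of the 46 models that fell with the Brachyury guide, 29 also differed among the replicate numbers. Of all 11953 tested models 8772 (73.4%) did, so this is not a trait particular to the fallen models. The median log2 fold change of the 46 was -1.49 in pair 1, -1.26 in pair 2 and -1.11 in pair 3, and these models were chosen on the same libraries.

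Libraries with the same replicate number deviated together, with correlations of 0.82 to 0.88. A difference in sequencing depth is argued against, since the lowest correlation was 0.82 after every library was thinned to the smallest total. A few variable genes are argued against too, since it was 0.72 without the 1196 models that varied most. A shared spawning, day, parents or developmental timing may lie behind the pairs, but the labels name none of them, and no biological explanation was tested.

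The blocked calls were mostly falls. Measured from the median difference of each pair, 29 models were at least 2-fold lower in all 3 pairs and 4 higher (87.9% lower). A factor per library does not move this share, so relative to the median model the authors' scaling is argued against. The counts were the same without that step, and the check cannot tell whether the median model itself changed. For the smaller falls the authors' scaling stays open. At least 86.9% of the calls were lower in each of 5 blocked fits with other scalings, but these moved the median log2 fold change by 0.002 at most and so decide nothing. Whether 1 pair carries the asymmetry was not settled by the bounds set beforehand, although falls outnumbered rises whichever pair was left out. Without pair 1, 71.4% of the 49 models changed at least 2-fold the same way in both other pairs were lower (35 models), between the bounds set beforehand, and the shares without pairs 2 and 3 were 76.1% and 75%. The guide itself, which the design names, remains open as a biological explanation and was not separately tested.

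Of the 10 splits of the 6 libraries into 3 and 3, all 10 gave as many unblocked limma calls as the real one, which gave 0, and the highest of the others was 0. No split can give fewer calls than 0, so this comparison had only 1 possible outcome and decides nothing. With 10, the splits are also too few for a share under 0.05. Up to 2475 models had an unadjusted p under 0.05 in splits that kept 2 libraries of a number together, against 60 in the real split, which points to the structure by replicate number. In the other splits that part all 3 pairs, as the real one does, this count was 2, 1 and 6. Among the 4 splits that part all 3 pairs, only 1, the real one, gave as many blocked calls (48), and the highest of the others was 0. These 4 splits are likewise too few for a share under 0.05.

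A hypothesis that the fallen models lie together in the genome was tested through the prefix of their identifiers. The prefix is the identifier without its last number. Models under the same prefix count alike however far apart they are, so closeness within a prefix was not measured. The 46 models held 44 pairs with the same prefix, and level-matched random lists had a median of 41 (permutation test with 100000 resamples, p = 0.42). The test leaves the hypothesis open, because the number of pairs lay within the central 95% of the random lists, 24 to 67.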
